A study of Homo sapiens with 3 samples.

How the data were processed

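MicroRNAs were measured in total RNA of the human non-small cell lung cancer cell line NCI-H1299, in parental cells (1 array) and in 2 cell clones in which the DICER1 gene had been deleted with CRISPR/Cas9 (1 array per clone). Per the labels' protocols, total RNA was prepared with the miRNeasy kit, and 0.5 µg per sample was labelled with Cy3 and hybridised to an Agilent human miRNA microarray. Per the labels, the deletion had been checked by sequencing and immunoblotting. DICER1 codes for a protein, and its own transcript is not measured by a miRNA array, so the labels of the clones could not be checked in these values.

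The authors deposited the scanner output of each array, with 1 line per spot, and the values used here are linear spot intensities. Per the file headers, the intensities were extracted with Agilent Feature Extraction 12.0.3.1, with the background subtracted and spatial trends removed within each array, and without any scaling between arrays. The submitters' processing notes name version 9.1 of the same software. The deposited value table holds the summed intensity per miRNA that the scanner software gives, rounded to 1 decimal, unscaled and not centred, with a median of 0.1 on each array, which is the value the software writes where a miRNA is not detected. The largest difference between that table and the scanner files was 0.05 on each array. Other deposited tables repeat the same measurements and were not used. All 3 arrays lay on 1 slide and were read in 1 scan.

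Each array held 50980 spots for 2549 human miRNAs, 1000 negative control spots and 1164 positive control spots. The miRNAs were represented by 5893 probes, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. MiRNA names are those of the array design. Probes of family members that differ by few bases can bind each other's miRNAs, so values within such families are not independent. No genome coordinates are given, because the files do not place the probes on the genome and no genome sequence was used here.

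The background-subtracted intensities of the spots of a probe were averaged after spots with an outlier flag were left out (1278 to 1332 flagged spots per array). No spot was saturated (0 on each array). A probe was called well above background on an array when most of its spots were, by the scanner software's call, and a miRNA was called detected when any of its probes was. Each array was divided by its 75th percentile over the 482 probes well above background on all 3 arrays, with factors of 1.15 for the parental array, 0.929 for clone 1 and 0.939 for clone 2. Scaled intensities were then raised to a common floor of 12.1 (log2 3.59), the highest of the 3 arrays' lowest signals above background, and put on the log2 scale. The value of a miRNA was the mean over its probes well above background on at least 1 array. At the floor a miRNA has no measured level, and values there have no order.

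The clones were compared with the parental array with limma (lmFit and eBayes, Benjamini-Hochberg adjustment over the 478 miRNAs detected on at least 1 array, threshold 0.05). The parental group has 1 array, so the spread came from the 2 clones (1 residual degree of freedom, moderated with 2.11 prior degrees of freedom and a prior SD of 0.17 on the log2 scale) and the parental array was assumed to vary like them. MiRNAs at the floor on both clones show no measured spread and took the prior variance alone. P-values therefore measure the spread between 2 clones of 1 cell line. No second parental array gives the spread of the parental cells or of the labelling. For a miRNA detected on the parental array and on neither clone, the change is given as a lower bound, "at least N-fold": the parental signal over the clones' mean, with each probe on each array at the higher of that array's lowest signal above background and its own signal. The reverse was done for miRNAs detected on both clones and not on the parental array. A fitted change of such a miRNA depends on the floor.

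The analysis was tested on simulated data with the same 478 miRNAs, 3 arrays and 200 changed miRNAs in each of 20 runs. limma called 98.8% of the miRNAs lowered by 4 on the log2 scale, 91.6% of those lowered by 2, 48.4% of those lowered by 1 and 51.7% of those raised by 1, and 3.32% of its calls were false. The simulated signals were kept above the floor, and their spread was drawn from limma's fitted prior, the same for the parental array as for the clones. These rates hold under those assumptions and do not test them, so they do not give the error rate of the real calls.

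Before the data were examined, 14 lists of miRNAs were fixed by name, as well as a split of the human miRNAs by the number in their miRBase name at 1000, which sets earlier entries against later ones. The lists were the let-7 family, the miR-17-92 cluster with its paralogs, the miR-15/16 family, the miR-23/27/24 clusters, the miR-29 and miR-30 families, and the miR-125/99/100/10 group. The others held growth-promoting and growth-restraining miRNAs of lung cancer cells, the miR-200 family, miRNAs of blood cells and serum, of muscle and neurons, and of pluripotent cells, miRNAs made without DICER1 or DROSHA, and miRNAs that overlap tRNA, snoRNA or rRNA. For each list with at least 3 detected members the median change was set beside 10000 random lists of the same size matched on mean signal, as a description of these arrays. The mean was taken over all 3 arrays, clones included. Random lists were drawn from all 478 detected miRNAs, of which 243 were numbered 1000 or above. The rule for the miRNAs named was also fixed beforehand. It takes the 10 brightest on the parental array, the 10 brightest of those detected there and on neither clone, and the 5 largest falls and rises among called miRNAs detected on all 3 arrays. It adds the 5 brightest on the clones, up to 5 detected on both clones and not on the parental array, the 3 that differed most between the clones, the 3 brightest of each list, and miR-451a, miR-320a, miR-484 and miR-877-5p. Arms of 1 precursor were paired by name. The relation between arms and parental brightness was described with a Mantel-Haenszel odds ratio over 4 classes of equal size by parental signal.

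Alternatives were the 75th or 90th percentile of all probes, quantile normalization, scaling to spike-in controls or no scaling, and normexp background correction with an offset of 50. The software's summed signal per miRNA, the deposited value table, the brightest probe per miRNA and a floor 2 times as high were also tried. Further alternatives were a restriction to miRNAs detected on all 3 arrays, no filter, the software's own detection call, a variance trend in eBayes, and each clone left out. Slide as a block was not run, because there was 1 slide. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The number of arrays limits the precision of every comparison.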

Results

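The data comprised 3 single-colour miRNA arrays of NCI-H1299 cells, a line derived from a human non-small cell lung cancer. One array held RNA of parental cells and 2 held RNA of separate DICER1 knockout clones. DICER1 is the RNase III enzyme that cuts hairpin precursors into mature miRNAs, and the comparison asked how the miRNA content of the cells differed without it. The share of miRNA spots well above background was 14.9% on the parental array, 11.3% for clone 1 and 10.97% for clone 2.

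Fewer miRNAs were detected in the knockout clones than in parental cells. Of the 2549 human miRNAs on the array, 424 were detected on the parental array, 329 in clone 1 and 314 in clone 2. In all, 138 miRNAs, 32.5% of those on the parental array, were detected on neither clone. In the other direction, 31 were detected on both clones and not on the parental array. On all 3 arrays 272 were detected. The summed, unscaled signal of all human miRNAs was 82.8% of the parental sum in clone 1 and 87.3% in clone 2, from equal amounts of labelled RNA. For the miRNAs with a miRBase number below 1000, which include the well-studied families, the sums were 13.0% and 13.5% of the parental sum, and their share of all signal was 13.5% on the parental array and 2.12% and 2.09% on the clones. For those numbered 1000 or above the sums were 93.7% and 98.8% of the parental sum. Most of the signal on every array came from miR-7975 and miR-7977, and without these 2 the sums over all miRNAs were 58.6% and 66.1% of the parental sum. Sums have no replicate of the parental array and were not tested. The spike-in controls above background lay between 0.846 and 1.03 times the parental signal on the clones. The sums over all miRNAs are near the lower end of that range, so their fall may be technical.

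Most of the limma calls were lower in the clones. limma called 102 of 478 miRNAs lower and 13 higher at a Benjamini-Hochberg adjusted threshold of 0.05, so that 88.7% of the calls were lower. Of the 102, 73 were detected on neither clone. Those at the floor on both clones have no measured clone spread, and their p-values rest on the prior variance and the single parental value. In both clones 119 were at least 2-fold lower and 21 at least 2-fold higher than on the parental array. The split depended on the scaling. The 2-fold counts were 105 lower and 56 higher with the 90th percentile of all probes, and quantile normalization turned their direction, with 99 lower and 116 higher. Lower calls made up 66.4% of all calls (79 lower, 40 higher) with that percentile and 75% (6 lower, 2 higher) with quantile normalization. The median change of the 272 miRNAs detected on all arrays was 0.27 on the log2 scale, against 0.01 without scaling and 1.00 with quantile normalization, and single changes should be read relative to that shift. Without a filter on dim miRNAs, limma called 0 of 2549 miRNAs in either direction, with 170 at an unadjusted p under 0.05.

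**Figure D1:**
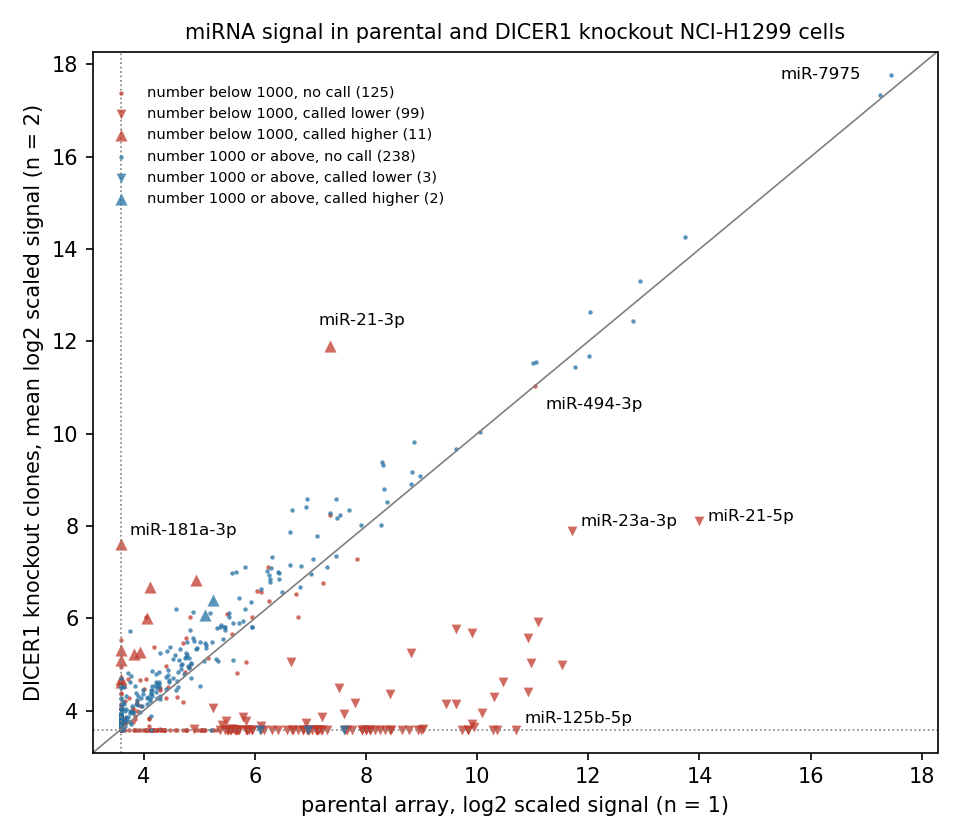
Log2 scaled signal of the 478 detected miRNAs on the parental array (x axis) against the mean of the 2 DICER1 knockout clones (y axis), coloured by miRBase number, with triangles for limma calls; dotted lines mark the floor at 3.59 and the diagonal marks equal signal. The 99 lower calls numbered below 1000 mostly lie along or near the floor, with miR-21-5p and miR-23a-3p above it, and most points numbered 1000 or above lie near the diagonal.

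MiR-21-5p, an abundant miRNA of many carcinomas, gave the brightest signal of the miRNAs numbered below 1000 in parental cells. Its log2 signal was 14.00 on the parental array and 8.11 ± 0.26 (SD, n = 2) on the clones, a change of -5.89 (SE 0.25, limma adjusted p = 0.00543) that left 1.69% of the parental signal. MiR-23a-3p, from a cluster with miR-27a and miR-24, fell by 3.82 (SE 0.20, limma adjusted p = 0.00679) and kept 7.09%. These were the only 2 of the 10 brightest miRNAs on the parental array that were called. The other 8 were miR-7975, miR-7977, miR-5100, miR-1260a, miR-4286, miR-1260b, miR-7641 and miR-4284, with changes from -0.35 for miR-4286 to 0.61 for miR-1260b. Among the 40 brightest, 26 were numbered below 1000 and 25 of these were called lower. The exception was miR-494-3p, named here after its values were seen, with log2 signals of 11.04 on the parental array and 10.94 and 11.12 on the clones.

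Many bright miRNAs were no longer detected in either clone. The 10 brightest of the 138 were miR-125b-5p, miR-106b-5p, let-7a-5p, miR-15b-5p, let-7f-5p, miR-93-5p, miR-30a-5p, miR-22-3p, miR-26b-5p and miR-17-5p, all called lower by limma. MiR-125b-5p was at least 147-fold lower (limma adjusted p = 0.0131), miR-106b-5p at least 116-fold, let-7a-5p at least 109-fold, and miR-17-5p at least 43.1-fold. The bounds hold for the main signal alone, with each clone at its own array's lowest signal above background. At the common floor the folds of these 4 were 138, 109, 103 and 40.6. With normexp their log2 changes were -4.64, -4.31, -4.23 and -2.98. The calls of miR-17-5p and miR-26b-5p were each lost in 4 of 14 alternatives, with limma adjusted p up to 0.187. Over the 138 the median bound was at least 3.996-fold, and for 91 it reached 2-fold. For 10 the bound was under 1, so that no fold is given. The largest falls among miRNAs detected on all 3 arrays were those of miR-29b-3p (change -6.55, SE 0.37), miR-24-3p (-6.51, SE 0.18), miR-107 (-6.13, SE 0.18), miR-16-5p (-6.02, SE 0.17) and miR-100-5p (-5.92, SE 0.40), with limma adjusted p from 0.00449 to 0.0112. Their mean log2 signals on the clones ran from 3.95 for miR-107 to 5.04 for miR-100-5p, near the floor of 3.59. With normexp the changes of these miRNAs, in the same order, were -5.03, -4.67, -3.96, -4.09 and -4.50.

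Most detected members of the large families of broadly expressed miRNAs were called lower. In the let-7 family, which restrains growth and is a mark of differentiated cells, 7 of 9 detected members were called lower (8 when adjusted over the list alone) and 8 were on neither clone. Let-7i-5p (change -0.40, limma adjusted p = 0.336) and miR-98-5p (-1.47, limma adjusted p = 0.0650) were not called. Both were on neither clone, with parental log2 signals of 3.99 and 5.06. Their changes are set by the floor and do not show a smaller fall than that of the other members. The family's median change was -2.08, or -2.16 with members at their bound. All 11 detected members of the miR-17-92 cluster and its paralogs, which promote cell division, were called lower (11 adjusted over the list alone), with a median of -5.06, or -5.14 at the bound. Of these, miR-106b-5p and miR-93-5p were on neither clone, and miR-19b-3p fell by 4.21 (SE 0.28) and stayed detected on both. In the miR-15/16 family, known to slow the cell cycle, 4 of 6 were called lower (5 adjusted over the list alone), among them miR-16-5p, miR-15b-5p (at least 81.1-fold) and miR-15a-5p (at least 13.0-fold, with the call lost in 5 of 14 alternatives). The family's median was -3.40, and -3.44 at the bound, with miR-195-5p (-1.50, limma adjusted p = 0.0633) and miR-497-5p (-0.70, limma adjusted p = 0.181) not called. These 2 were also on neither clone, with parental log2 signals of 5.09 and 4.29, so that the floor sets their changes.

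All 5 members of the miR-23/27/24 clusters were called lower (5 adjusted over the list alone), with a median of -4.40, or -4.49 at the bound, and miR-27a-3p fell by 5.36 (SE 0.21). All 8 members of the miR-29 and miR-30 families were called lower (8 adjusted over the list alone), with a median of -4.91, or -4.95 at the bound. MiR-29 family members target collagen and other matrix transcripts. MiR-29a-3p fell by 5.16 (SE 0.41), and miR-29c-3p, detected in clone 2 and at the floor in clone 1, fell by 6.20 (SE 0.21), a value that depends on the floor. All 7 members of the miR-125/99/100/10 group were called lower (7 adjusted over the list alone), with a median of -3.19, or -3.27 at the bound, and miR-10a-5p was at least 30.2-fold lower, with its call lost in 4 of 14 alternatives. The medians of these lists stood at the percentiles 5.55 (let-7), 0.06 (miR-17-92), 0.66 (miR-15/16), 1.70 (miR-23/27/24), 0.00 (miR-29 and miR-30) and 3.63 (miR-125/99/100/10) of 10000 random lists matched on mean signal. Random lists mixed both number classes, so low percentiles also carry the difference between the classes and do not set these families apart from others numbered below 1000. The percentiles of the other lists come from the same mixed pool. The medians of all 6 lists were negative under every scaling tried.

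**Figure D2:**
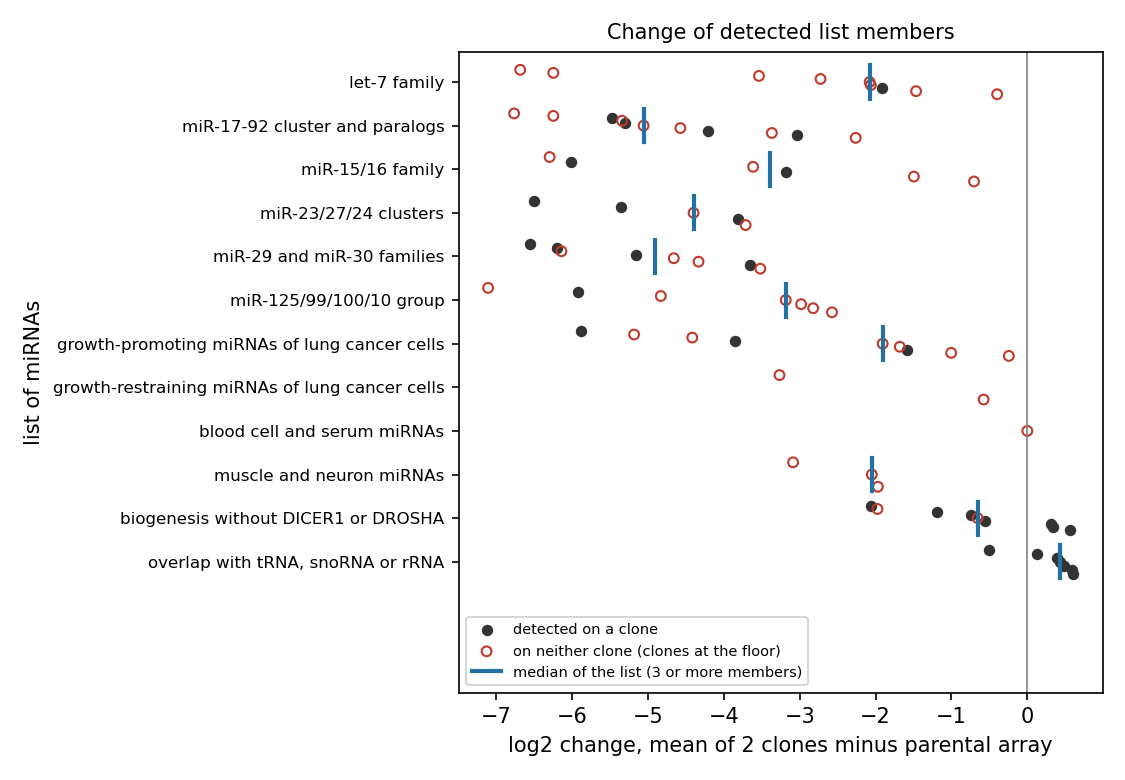
Log2 change, mean of the 2 knockout clones minus the parental array (x axis), of each detected member of 12 lists of miRNAs (y axis); open circles are members on neither clone, whose change is set by the floor, and bars are list medians. Medians run from -5.06 for the miR-17-92 cluster and its paralogs to 0.44 for miRNAs that overlap tRNA, snoRNA or rRNA.

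Of 9 miRNAs known to promote the growth of lung cancer cells, 6 were called lower (8 adjusted over the list alone), with a median of -1.91, or -1.99 at the bound, at percentile 0.67. MiR-221-3p fell by 3.85 (SE 0.22) and miR-31-5p was at least 38.6-fold lower, with its call lost in 4 of 14 alternatives. Of 10 miRNAs known to restrain such growth, 2 were detected on any array. MiR-126-3p was at least 10.2-fold lower (called, also over the list alone, with the call lost in 5 of 14 alternatives), and miR-218-5p, at 4.17 on the parental array and on neither clone, was not called. None of the miR-200 family of epithelial cells (0 of 6) and none of the miRNAs of pluripotent cells (0 of 8) was detected on any array. Of the miRNAs of blood cells and serum, 1 of 7 was detected, miR-223-3p, at the floor on the parental array. Of those of muscle and neurons 3 of 10 were detected, miR-9-5p, miR-9-3p and miR-128-3p, all called lower (3 adjusted over the list alone), with a median of -2.05, or -2.14 at the bound, at percentile 13.9. Their calls were lost in 5, 7 and 7 of 14 alternatives, with limma adjusted p up to 0.231, 0.336 and 0.350.

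Among miRNAs described as made without DICER1 or without DROSHA, 3 of 9 detected members were called lower (3 adjusted over the list alone) and 0 higher by limma. The list pools these 2 kinds, for which loss of DICER1 need not have the same effect, so its median and percentile describe neither kind alone. The called members were miR-320c, miR-320d and miR-320e, which belong to a family whose hairpins bypass DROSHA. MiR-320d fell by 2.06 (SE 0.17). MiR-320a had a change of -0.75 (SE 0.22, limma adjusted p = 0.126) and miR-320b one of -0.56 (SE 0.23, limma adjusted p = 0.207), and both turned positive with quantile normalization (0.47 and 0.78). MiR-484 was on neither clone, at least 1.67-fold lower and not called. MiR-451a, which is cut by AGO2 in place of DICER1, was detected in clone 1 alone, at 4.23. MiR-877-5p, a mirtron, was detected on no array. The remaining detected members had positive changes and were not called. They were miR-1225-5p (0.57) and miR-1224-5p (0.34, a value that depends on the floor), the latter on both clones and not on the parental array. The median of the list was -0.66 (-0.74 at the bound, percentile 0.89) and turned to 0.38 with quantile normalization. Most of its detected members are numbered below 1000, where the median over all detected miRNAs was -0.88. The low percentile, from random lists of both number classes, therefore does not show an unusual fall. Among 7 detected miRNAs whose sequence overlaps tRNA, snoRNA or rRNA, limma called 0 lower and 0 higher, also when adjusted over the list alone. Their median was 0.44 (0.49 at the bound, percentile 84.2), positive under every scaling, with changes of 0.39 for miR-1260a, 0.61 for miR-1260b and 0.49 for miR-3651.

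Most of the called rises were in 3p arms, the strand from the 3′ side of the hairpin. Of the 21 miRNAs at least 2-fold higher in both clones, 13 were 3p arms numbered below 1000, 7 were numbered 1000 or above, and 1 was miR-630 (change 1.98, SE 0.69, limma adjusted p = 0.157). MiR-21-3p, the partner strand of miR-21-5p, rose from 7.35 on the parental array to 11.90 ± 0.06 (SD, n = 2), a change of 4.55 (SE 0.18, limma adjusted p = 0.00498) or 23.5-fold. The other largest called rises among miRNAs detected on all arrays were miR-181a-2-3p (2.57, SE 0.20), miR-424-3p (1.94, SE 0.20), miR-16-2-3p (1.90, SE 0.28) and miR-30c-2-3p (1.40, SE 0.26, limma adjusted p = 0.0490). The call of miR-30c-2-3p was lost in 12 of 15 alternatives (limma adjusted p 0.0158 to 0.353), that of miR-16-2-3p in 8 of 15 (0.000987 to 0.267), and that of miR-424-3p in 5 of 15 (0.00209 to 0.187). Detected on both clones and not on the parental array were miR-181a-3p (at least 20.6-fold higher), miR-181b-2-3p (at least 4.22-fold) and miR-181b-3p (at least 3.66-fold), all called. Their calls were lost in 1, 6 and 4 of 14 alternatives, with limma adjusted p up to 0.0576, 0.215 and 0.192. With normexp their log2 changes were 1.80, 0.47 and 0.39, under these bounds. MiR-16-1-3p (at least 4.90-fold, limma adjusted p = 0.0757) and miR-155-3p (at least 3.16-fold, limma adjusted p = 0.0519) were not called. Of the 13 miRNAs called higher, 11 were 3p arms numbered below 1000 and 0 were 5p arms numbered below 1000. The other 2 were miR-4466 and miR-1207-5p, named after their values were seen.

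Among miRNAs numbered below 1000, 53 of 106 tested 5p arms were called lower and 0 higher, against 38 lower and 11 higher of 106 tested 3p arms. Of the arms detected on the parental array, 19 of 104 5p arms and 52 of 91 3p arms were also detected on both clones. The difference held across parental brightness, with a Mantel-Haenszel odds ratio of 5.33 (95% interval 2.76 to 10.3) over 4 brightness classes of the 195 arms, which are not replicates. In 52 precursors of any number with both arms detected on the parental array, the change of the 3p arm exceeded that of the 5p arm by a median of 1.10 in both clones and was above it in 34. Split by number, the medians for clones 1 and 2 were 2.69 and 2.77 in the 44 below 1000, and -0.21 and -0.18 in the 8 at 1000 or above. In the 13 precursors with both arms detected on all 3 arrays the medians were 0.53 and 0.59. These were 4.99 and 5.16 in the 8 below 1000, with means over the clones from -3.79 for miR-221 to 10.44 for miR-21, and -0.02 and -0.04 in the 5 at 1000 or above. The count of 34 differed with which arm was brighter in parental cells. The 3p change was above the 5p change in 32 of 40 precursors with a brighter 5p arm and in 2 of 12 with a brighter 3p arm. The change of an arm on neither clone is set by the floor. Where both arms were on neither clone, as for miR-183, this alone makes the brighter arm fall more, whichever side it comes from. The median of 1.10 and these counts therefore partly reflect the floor and do not by themselves show a difference between arms.

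**Figure D3:**
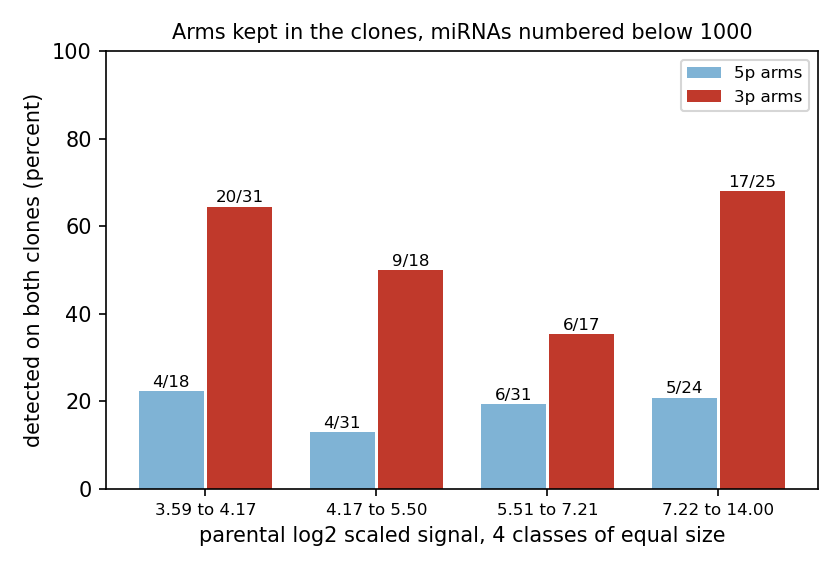
Percent of miRNA arms detected on the parental array that were also detected on both knockout clones (y axis), for 5p and 3p arms numbered below 1000, in 4 classes of equal size by parental log2 signal (x axis); labels give kept over all arms. In the brightest class 17 of 25 3p arms and 5 of 24 5p arms were kept.

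Few of the miRNAs with later miRBase numbers were called. Of 235 detected miRNAs numbered below 1000, 99 were called lower and 11 higher, 127 were lost from both clones, and the median change was -0.88. Of 243 numbered 1000 or above, 3 were called lower (miR-4291, miR-4324 and miR-4306), 2 higher, 11 were lost and the median change was 0.30. Adjusted over the list alone, 110 were lower and 14 higher below 1000, and 0 lower and 0 higher at 1000 or above. The brightest miRNAs of the clones were miR-7975, miR-7977, miR-5100, miR-1260a and miR-1260b, none of them called. Under every scaling the median stayed negative below 1000 and positive at 1000 or above, but its size depended on the method. Below 1000 it lay between -1.78 with the summed signal and -0.19 with normexp, and at 1000 or above between 0.045 with the higher floor and 0.94 with quantile normalization.

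The 2 clones resembled each other more than either resembled the parental cells. Across the 272 miRNAs detected on all arrays, which are not independent replicates, Pearson's r was 0.982 between the clones and 0.769 and 0.782 between the parental array and clones 1 and 2. Of 303 miRNAs detected on both clones, 12 differed by at least 2-fold between them, 8 higher in clone 1 and 4 in clone 2. The largest differences were those of miR-4532 (2.79-fold higher in clone 1), miR-630 (2.55-fold higher in clone 1) and miR-4763-3p (2.51-fold higher in clone 2). With 1 array per clone, a difference between clones has no replicate check.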

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

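The tests of scaling, of mixed-in parental RNA, of dim signal and of overlap with other small RNAs were chosen after the result was seen, while those of precursors and of GC content were written before their values were seen.

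Some positive control probes outside the miRNA comparison were brighter on both clones than on the parental array, by more than 2 standard errors of their spots on each array, an error that covers the spots of an array and not the labelling or the samples. The unscaled signal of the clones averaged 1.20 times the parental signal for the control probe hur_1, 1.08 times for hur_2, 1.19 times for hur_5, 1.34 times for hur_6 and 1.25 times for mr_1. It was 1.05 times for hur_4, within that error, and 0.831 times for the bright corner control. The spike-in controls above background lay between 0.846 and 1.03 times the parental signal. What RNA these control probes detect is not given in the sources used here.

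Signal was at least 2-fold higher in both clones for 13 3p arms numbered below 1000, of which 11 were called. The choice among the scalings tried does not account for these rises, since their median change was still 1.60 under the lowest, for all 13 and for the 11 called. This is a limited test, because the arms were picked for their rise under the main scaling. For those not detected on the parental array the change also depends on the floor. Precursor hairpins that DICER1 no longer cuts end in the 3p arm, and a candidate explanation is that such hairpins give signal on 3p probes. This was examined in 97 pairs of arms numbered below 1000 with a brighter 5p arm. The clones' 3p signal rose with the parental 5p signal once the parental 3p signal was taken out. The partial rank correlation was 0.23 (bootstrap 95% interval 0.02 to 0.42), and 0.20 over the 150 such pairs of any number. Some pairs share a 5p arm, as those of miR-16-5p and miR-181a-5p do, and many 3p arms lay at the floor on the clones. The pairs are therefore not independent, and the interval, whose lower end is close to no correlation, may be too narrow. Many 3p arms, such as miR-181a-3p and miR-16-1-3p, also lay at the floor on the parental array. Their parental level was therefore not fully taken out, which could by itself leave a positive correlation. A positive correlation could also come from such hairpins or from a mature 3p strand made by another route, since an array does not measure RNA length. Probe GC content as the cause called for probes of the 13 rising 3p arms to be clearly richer in GC than those of their 5p arms. The median difference was instead -7.23 percentage points (95% interval -13.1 to 5.65), the same for the 11 called. This argues against a large excess of GC, while the interval still allows a small one.

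Bright miRNAs that fell kept unequal parts of their parental signal. On clone 1 the percent kept ran from at most 0.643% for miR-125b-5p to 7.60% for miR-221-3p, and on clone 2 from at most 0.724% for miR-125b-5p to 7.56% for miR-23a-3p, among the 20 brightest of these miRNAs. Parental cells or RNA mixed into the clone samples could leave only 1 common percent, and the highest exceeded the lowest bound by at least 10.4 times on each clone, so mixing is argued against as the whole source. A small share of mixed-in RNA, up to the lowest of these bounds, stays open.

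MiRNAs numbered 1000 or above mostly kept their signal. Dim signal is argued against: of 33 with a parental log2 signal of 7 or more, 3.03% fell at least 2-fold in both clones, against 91.8% of 61 numbered below 1000. GC-rich probes that bind RNA other than the miRNA may account for part of it. The median GC content of probes of miRNAs numbered 1000 or above was higher by 19.2 percentage points (95% interval 15.2 to 21.8). Among the 216 miRNAs numbered below 1000 on the parental array the change rose with probe GC (Spearman 0.363 across miRNAs, 95% interval 0.232 to 0.472). Of these 216, 127 were on neither clone, so that the floor and the parental signal largely set their change. Parental brightness was not taken out, so this correlation cannot tell binding of other RNA from a link between GC and brightness. Sequence shared with tRNA, snoRNA or rRNA is also open for the detected members of that list numbered 1000 or above. The median change of 0.44 covers all 7 detected members, including miR-664a-3p and miR-664b-3p, which are numbered below 1000. That some miRNAs numbered 1000 or above are made without DICER1 was not tested.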

How the results depend on the processing

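All alternatives were fixed before the data were examined except the one in which miRNAs at the floor on both clones keep their residual, which was chosen after seeing the data. No paired analysis was possible because the parental group has 1 array. Slide as a block was not run, since all arrays shared 1 slide. Leaving out a clone leaves 1 array against 1, which gives values and no test. Dim signal is a limit: miRNAs near the floor have small bounds whatever their true change.

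The count of 102 miRNAs called lower became 33 with normexp, 24 with a floor 2 times as high, 24 of the 272 detected on all 3 arrays, 55 with the software's detection call, 6 with quantile normalization and 0 without a filter, and stayed within 1.5 times under the other alternatives. The count of 13 called higher became 7 without scaling, 40 with the 90th percentile of all probes, 2 with quantile normalization, 4 with normexp, 22 with the value table, 31 with the brightest probe, 3 with the higher floor, 3 for miRNAs on all 3 arrays, 5 with the software's detection call, 0 without a filter, and 30 with the residual kept. Testing 2549 miRNAs, most of them at the floor, enters the adjustment of the unfiltered count. Requiring detection on all 3 arrays leaves out by construction the 73 lower calls on neither clone, and higher calls missing from the parental array. The causes of the other shifts were not tested. The count of 119 at least 2-fold lower became 70 with normexp and 26 for miRNAs on all 3 arrays, which leaves out lost ones by construction. The count of 21 at least 2-fold higher became 42 and 56 with the 75th and 90th percentile of all probes, 13 without scaling, 116 with quantile normalization, 51 with the software's summed signal, 53 with the value table, 4 with normexp and 10 with the higher floor. Without a clone it lay between 31 and 41, since 1 clone then had to pass.

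The median change below 1000 (-0.88) and at 1000 or above (0.30) kept its sign under the scalings, signals, probe summary and floor tried and without either clone; it was not computed for the other filters, detection calls or variance models. The values were -0.44 and 0.58 with the 75th percentile of all probes, -1.17 and 0.064 without scaling, -0.39 and 0.64 with the 90th percentile, -0.35 and 0.94 with quantile normalization, and -1.07 and 0.15 with spike-ins. They were -1.78 and 0.42 with the summed signal, -0.19 and 0.14 with normexp, -1.77 and 0.43 with the value table, and -0.22 and 0.045 with the higher floor. With the brightest probe the first was -1.24. Without a clone they lay at -0.89 (both clones) and between 0.23 and 0.30. The list of miRNAs made without DICER1 or DROSHA turned from -0.66 to 0.38 with quantile normalization; the cause was not tested.

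The difference between arms (1.10) depends on the floor for arms on neither clone. It was 0.98 over 75 precursors with the summed signal and 1.33 with the brightest probe. Over the 13 precursors with both arms on all 3 arrays it was 0.53 in clone 1 and 0.59 in clone 2. These 13 mix 8 below 1000, with medians of 4.99 and 5.16, and 5 at 1000 or above, with -0.02 and -0.04, a split made after seeing the data. MiRNAs at least 2-fold apart between clones (12 of 303) became 32 of 419 with the summed signal and 30 of 419 with the value table. The summed signal below 1000 became 14.1% and 14.2% of the parental sum with the local background subtracted.

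Of the 59 named miRNAs, 39 were called. All of them kept their direction wherever they were tested. Calls were lost by 39 without a filter, 32 with quantile normalization, 17 with the higher floor, 15 with normexp, 9 with the software's detection call, 8 with the residual kept, and 2 of the 17 tested when detection on all 3 arrays was required. At most 3 of 39 were lost under any other alternative. MiR-21-3p ranged from 4.09 to 5.27 (limma adjusted p 0.000350 to 0.0520) and miR-21-5p from -6.18 to -4.94 (0.000310 to 0.0577). These 2 were among the steadier ones: the log2 change of 28 of the 39 moved more than 1.5 times under at least 1 alternative, and the change of 33 was smallest with normexp. MiR-181a-3p ranged from 1.80 with normexp to 6.48 with the summed signal.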

Other observations

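The test of shared probe sequence was chosen after the result was seen.

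The 4 miRNAs numbered 1000 or above that fell at least 2-fold in both clones were miR-4291 (at least 17.2-fold lower), miR-4324 (at least 10.9-fold), miR-4306 (at least 6.04-fold) and miR-4317 (at least 3.28-fold, not called, limma adjusted p = 0.0556), against a median change of 0.30 in their class. A hypothesis is that their probes may have measured better-known miRNAs of similar sequence. Probes of miR-4291 share a run of 14 bases with probes of miR-24-3p, those of miR-4317 a run of 12 with miR-23b-3p, those of miR-4306 a run of 11 with miR-185-5p, and those of miR-4324 a run of 11 with miR-125b-5p. Partners were searched only among miRNAs numbered below 1000 that were called lower, so their fall is no result of the search. Runs shared with other miRNAs were not computed. Where partners tied, a single name is given. The longest run shared with a miRNA called lower and numbered below 1000 was 11 to 14 bases in these 4 and at most 9 in the other 204 miRNAs numbered 1000 or above that were detected on the parental array (medians 11.5 and 6, exact permutation test of the mean run, two-sided, p = 1.32e-08, across miRNAs). The likeness was noticed in these miRNAs first, so that p is no independent evidence. A shared run was not enough for signal: of 11 miRNAs numbered 1000 or above on the array with a run of at least 11 bases, 7 were not detected in parental cells. Transcription of these 4 miRNAs themselves was not tested.

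In the miR-320 family the changes of 5 members were negative, except that those of miR-320a and miR-320b turned to 0.47 and 0.78 with quantile normalization. MiR-320c (change -1.20, SE 0.20, limma adjusted p = 0.0409), miR-320d and miR-320e (at least 4.17-fold lower, limma adjusted p = 0.0157) were called lower, and miR-320a and miR-320b, with changes of -0.75 and -0.56, did not pass the threshold. Whether the members differ from each other was not tested, and their probes can bind each other's miRNAs.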
